A study of Halothece sp. PCC 7418 with 2 samples.

How the data were processed

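Total RNA of Halothece sp. PCC 7418 was extracted with TRIzol LS and sequenced by a service provider, per the labels' protocols, from a culture acclimated to 0.5 M NaCl and a culture acclimated to 2.5 M NaCl; each group holds 1 library. The labels' protocols give at least 8 days of acclimation, whereas the time labels are 0 h and 24 h, and this difference was not resolved, so salinity cannot be separated from any other difference between the 2 cultures. Bowtie is named in the submitters' processing notes; its version, the counting tool and whether counting used strand are not given in the sources used here. Coordinates are those of the table, on the organism's chromosome.

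The read counts are raw whole-number counts per feature, as deposited by the authors. The FPKM values were deposited by the authors, per kilobase of feature scaled to a single total per library, and these totals were recovered as 20281846 reads at 0.5 M and 19062799 at 2.5 M. The log2 values were deposited by the authors as log2(CPM + 1), and they give a single effective size per library, 19476361 and 17761215. The fold changes are signed scores deposited by the authors, the ratio where a feature is higher and minus the inverse ratio where it is lower. The raw and adjusted p-values were deposited by the authors over all 3730 features they tested. The table holds 1193 of these, all with a fold change of at least 2 in size and a raw p under 0.05. A second table holds the same 1193 features with the direction turned round, and was not used further. The authors' Gene Ontology list was used for the number of listed features per term.

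The plan, fixed before the data were examined, was TMM scaling over all genes. Because the table is a selected list, TMM factors computed on it would be distorted, so the effective sizes recovered from the authors' log2 values were used instead; TMM and DESeq2 factors from the listed features were run as alternatives. No document used here states how the authors obtained these sizes. The log2 ratio of the 2.5 M over the 0.5 M library was computed after adding 0.5 reads to each count in proportion to library size. A feature was counted as higher or lower when its ratio was at least 2-fold and both libraries together held at least 20 reads of it. Counting intervals are exact conditional binomial (Clopper-Pearson) intervals at 95%. With 20281846 and 19062799 reads, the interval of a ratio is wide where a gene has few reads and narrow where it has many; reads without molecular identifiers are not independent molecules, so the intervals cover counting error only.

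No test of the conditions was made, since there is 1 library per group. The authors' raw p-values were matched by edgeR's exact test with an assumed biological coefficient of variation of 0.1, the largest difference being 1.37e-08 in log10 p. This value was inferred from the p-values and was not measured on replicates, since each group holds 1 library, so no p-value is used as evidence. With an assumed coefficient of 0.2, 458 higher and 725 lower listed features had a raw p under 0.05, with 0.3, 289 and 515, and with 0.4, 127 and 296. The features at 0.2 and those counted at 2-fold were both 1183 in number and shared 1177.

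Fixed gene lists, 32 in number, were matched on the product text and symbol of the table. For the 22 lists with at least 3 listed members, the median log2 ratio was set against 10000 random lists of the same size matched on 20 expression bins, and called apart below percentile 2.5 or above 97.5. Since the table leaves out ratios under 2-fold, medians lie beyond 1 or below -1 on the log2 scale unless a list is evenly split, so the number of members in each direction is given as well. Named genes followed a rule fixed in advance: among genes with at least 100 reads over both libraries the 12 highest and 12 lowest ratios, the 5 most abundant coding genes per library by FPKM, and for each list the 2 highest and 2 lowest members or all members of lists of up to 6, of which the text names a part. Other members named in the text, such as clpB, groL, groES, htpG, grpE and PCC7418_RS12535, and the groups in the closing section were chosen after their values were seen, as were the gene length comparison and the random lists matched on length.

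The ratio and list steps were tested on simulated counts for 1193 features, of which 200 were changed 4-fold. Of the 200, 199 were called at 2-fold, as was 1 of the 993 unchanged features, and 95.2% of the intervals held the true ratio. Of 200 random lists 9 came out apart, which is close to the 5% set by the percentiles. The simulated features varied independently and most were unchanged, unlike the listed ones, so the simulation does not show how the list percentiles hold for these data. Alternatives covered the scaling, the minimum of reads, the prior, the library sizes without the 10 most abundant listed genes, the list statistic and the random lists. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.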

Results

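The data were 2 RNA-seq libraries of Halothece sp. PCC 7418, a halotolerant unicellular cyanobacterium, from wild-type cultures acclimated to 0.5 M NaCl (low salinity) or 2.5 M NaCl (high salinity), with 1 library per group. The question was how transcript levels differ between cells acclimated to low and to high salt. The authors' deposited table lists 1193 features with their read counts, and these hold 4170825 reads of the 0.5 M library and 3269513 reads of the 2.5 M library. The library totals implied by the FPKM values were 20281846 and 19062799 reads. The listed features are a selection: each has a fold change of at least 2 in either direction and a raw p under 0.05 in that table, out of 3730 features the authors tested, so every count of members below covers listed members only, and a gene that is not named was not necessarily unchanged. All differences are between 2 single libraries and have no replicate check; the intervals in brackets are 95% counting intervals of the ratio and cover counting error only. The labels also carry a time of 0 h for the 0.5 M library and 24 h for the 2.5 M library.

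More features were lower than higher in the 2.5 M library. Of the 1186 features with at least 20 reads over both libraries, 458 were at least 2-fold higher and 725 at least 2-fold lower, and the whole counting interval lay beyond 2-fold for 342 and 527 of them. Differences of at least 4-fold were found in 72 features that were higher and 217 that were lower, and of at least 8-fold in 17 and 53. The split depends on the scaling. With size factors computed by DESeq2 from the listed features alone, 460 were at least 2-fold higher and 176 at least 2-fold lower. With TMM factors from the same features the numbers were 460 and 343. Both methods centre a list that lacks the features under 2-fold and in which 61.4% of features were lower. The listed features alone cannot show which scaling holds.

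**Figure D1:**
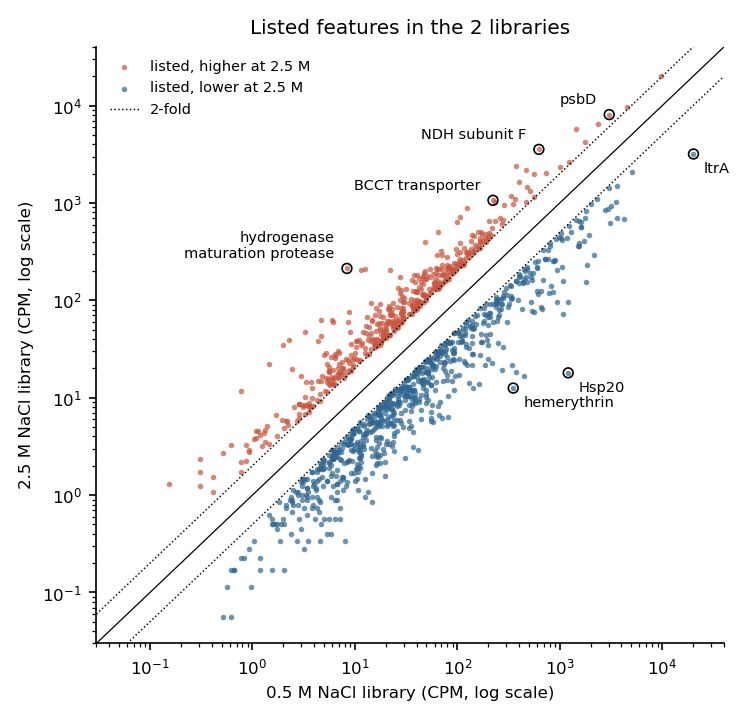
CPM values of the 1193 listed features in the 0.5 M library (x axis, log scale) and the 2.5 M library (y axis, log scale), with the authors' library sizes; each point is a feature, the solid line marks equal levels and the dotted lines 2-fold. The empty band along the diagonal is the authors' threshold, and the Hsp20 gene lies farthest below it, at 67.0-fold lower.

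Chaperone transcripts went both ways, with a low median in the 2.5 M library. Of 11 listed chaperone and heat-shock genes 8 were lower, with a median log2 ratio of -1.76 that stood at percentile 1.01 of 10000 random lists of the same size matched on expression. The share of lower members was not apart, at percentile 88.7, where 61.4% of all listed features were lower. The small heat-shock protein gene PCC7418_RS07305 (Hsp20/alpha crystallin family, chromosome positions 1616347 to 1616796) had 23545 reads at 0.5 M and 320 at 2.5 M, which is 67.0-fold lower (60.1 to 75.2) and the lowest ratio among genes with at least 100 reads. The other listed Hsp20 gene, PCC7418_RS03770, was 8.13-fold lower (7.87 to 8.40). The genes of clpB, both listed groL copies, groES, htpG and grpE were lower too, whereas both listed dnaK copies and dnaJ were higher, dnaK PCC7418_RS13095 by 3.09-fold (2.90 to 3.31) and dnaJ by 2.62-fold (2.47 to 2.78). The chaperone median was not apart when the list was shifted along the gene order, at percentile 3.63, nor with genes of at least 500 nt only, an added setting in which 7 members had a median of -1.04 at percentile 22.5.

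Genes for inorganic carbon uptake and for part of the NDH-1 complex, which carries out cyclic electron flow and CO2 uptake in cyanobacteria, were higher in the 2.5 M library. Both listed genes of carbon concentration and fixation were higher: the CO2 hydration protein gene PCC7418_RS17200 by 4.66-fold (4.55 to 4.77), from 9221 to 39173 reads, and the sodium-dependent bicarbonate permease gene PCC7418_RS00280 by 2.08-fold (2.07 to 2.09), from 187785 to 356137 reads. The 2 genes beside the CO2 hydration protein gene on the minus strand, NADH-quinone oxidoreductase subunit M (PCC7418_RS17205) and NAD(P)H-quinone oxidoreductase subunit F (PCC7418_RS17210, positions 3766300 to 3768129), were 6.35-fold (6.19 to 6.51) and 5.68-fold (5.57 to 5.79) higher. Of 5 listed NDH-1 genes 3 were higher and 2 lower, with a median log2 ratio of 1.63 at percentile 98.3 of matched random lists. The lower ones were nuoK, 2.72-fold (2.62 to 2.82), and ndhL, 2.72-fold (2.49 to 2.97), which are 312 and 213 nt long. The mean of the NDH-1 log2 ratios, 0.78, stood at percentile 93.9 and was not apart.

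**Figure D2:**
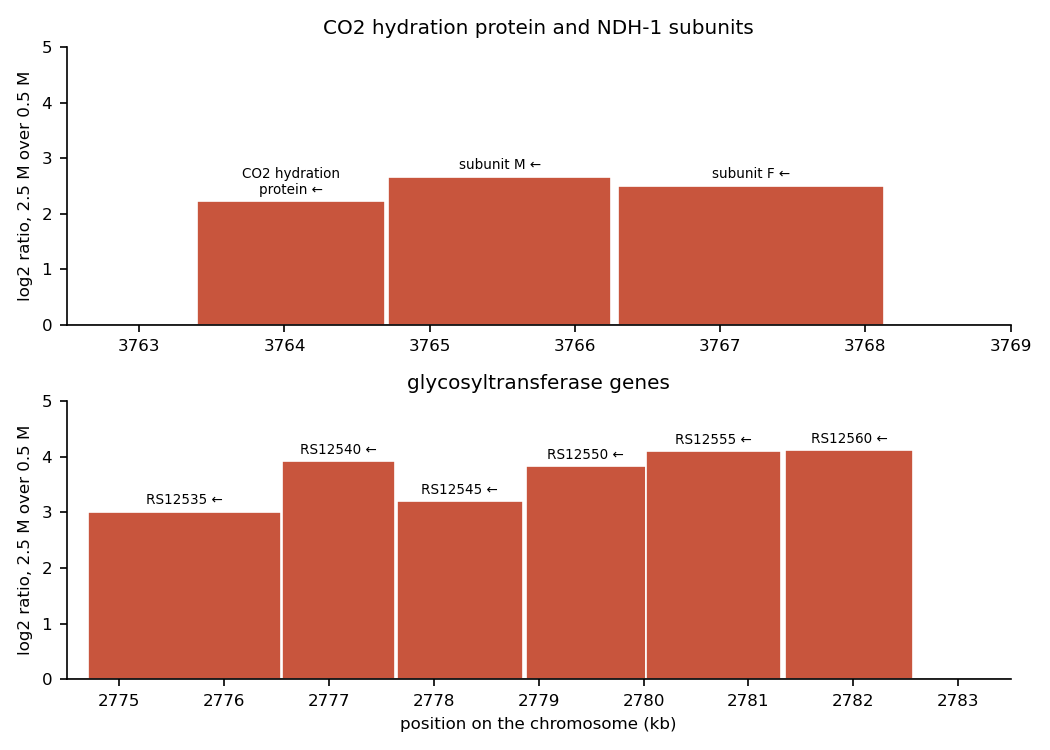
Log2 ratio of the 2.5 M over the 0.5 M library (y axis) of listed genes along 2 stretches of the chromosome (x axis, kb); each bar spans a gene and the arrow gives its strand. The CO2 hydration protein and the 2 NDH-1 subunit genes beside it have log2 ratios of 2.22, 2.67 and 2.51, and the genes of the glycosyltransferase stretch, PCC7418_RS12535 to PCC7418_RS12560, reach 4.12.

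Among genes for compatible solutes, small molecules that balance the osmotic pressure of salt, those for uptake were higher and 1 for synthesis was lower. The BCCT family transporter gene PCC7418_RS15085, of a family that takes up betaine and related solutes, was 4.78-fold higher (4.62 to 4.94), from 4342 to 18923 reads, and proX, the binding protein of a glycine betaine/proline transporter, was 2.32-fold higher (2.02 to 2.68). The gene ggpS, for the enzyme that starts glucosylglycerol synthesis, was 2.54-fold lower (2.47 to 2.61). The median over these 3 genes was not apart from random lists, at percentile 83.4. Both listed genes of serine and one-carbon supply were higher, serine hydroxymethyltransferase (PCC7418_RS07570) by 4.04-fold (3.94 to 4.14) and folD by 3.27-fold (2.96 to 3.63). No listed gene matched the lists for glycine betaine synthesis, sodium/proton antiport or potassium transport, and 4 listed mechanosensitive channel genes were split, 2 higher and 2 lower.

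Photosynthesis genes went both ways. Of 13 listed photosystem II genes 10 were lower, among them psbU at 7.04-fold (6.73 to 7.37), while psbD, for the D2 reaction centre protein, was 2.66-fold higher (2.64 to 2.69), from 59185 to 143631 reads. Of 4 listed psbA copies, for the D1 protein, 2 were higher and 2 lower: PCC7418_RS14700 was 2.15-fold higher (2.13 to 2.17), PCC7418_RS19100 was 2.38-fold higher (2.35 to 2.41) and PCC7418_RS03535 was 11.8-fold lower (11.3 to 12.2), and whether these copies share sequence was not checked, so the single values are uncertain. Lower members were also the majority in photosystem I (3 of 4), in cytochrome b6f and electron carriers (6 of 8) and in ATP synthase (2 of 2). The higher photosystem I member was PCC7418_RS01570, for a photosystem I accumulation factor, whereas the lower ones were for reaction center subunits. In chlorophyll and heme synthesis 5 of 8 were lower, and chlP, for geranylgeranyl reductase, was 4.01-fold higher (3.96 to 4.06). That list did not match the ferrochelatase gene PCC7418_RS06680, which was 16.5-fold higher (14.5 to 18.9). The medians of photosystem I, photosystem II, cytochrome b6f and electron carriers, and chlorophyll and heme synthesis stood at percentiles 20.9, 17.4, 54.0 and 13.9 of random lists and were not apart, and 61.4% of all listed features were lower. With coding genes of at least 500 nt only, the median over the 6 remaining photosystem II genes was -0.0066, against -1.27 over all 13. The listed phycobilisome gene, a rod-core linker, was 2.32-fold lower (2.27 to 2.37), and zds, of carotenoid synthesis, was 2.56-fold higher (2.35 to 2.80). The chlorophyll a/b binding protein genes PCC7418_RS17760, with 15 and 209 reads, and PCC7418_RS17765, with 75 and 221 reads, were 14.8-fold (9.05 to 27.8) and 3.22-fold (2.48 to 4.26) higher; they put the photoprotection list at percentile 97.7, but its other member, scpB, belongs to chromosome condensation and matched the list by its symbol alone. The list was not apart when shifted along the gene order, at 94.8, or against random lists matched on length too, at 95.5.

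In nutrient and carbon metabolism, 4 of 5 listed phosphate genes were higher, among them ppk1, for polyphosphate kinase, at 3.74-fold (3.47 to 4.04). Genes matched for nitrogen were split 5 to 5, or 4 higher to 5 lower without a bifunctional ornithine acetyltransferase/N-acetylglutamate synthase gene (PCC7418_RS16075) matched by accident, which turns the median from 0.03 to -1.005, as does a minimum of 100 reads. The genes gltB and gltD, for the subunits of glutamate synthase, were 4.16-fold (4.06 to 4.26) and 5.32-fold (5.03 to 5.63) lower. Iron and metal transport genes were split 7 higher to 9 lower, sulfur genes 2 to 1, oxidative stress genes 7 to 5 and proteases 3 to 3. Of 9 listed genes of glycogen and central carbon metabolism 7 were lower, with glycogen phosphorylase (PCC7418_RS14170) 11.6-fold (9.56 to 14.3) and pyk, for pyruvate kinase, 5.31-fold (5.07 to 5.56) lower, whereas class I fructose-bisphosphate aldolase was 3.56-fold higher (3.46 to 3.66). Of 9 listed ribosomal protein genes 8 were lower, L32 by 8.50-fold (7.81 to 9.28). The single listed sigma factor gene and the single gene matched for mycosporine-like amino acid synthesis, a 3-dehydroquinate synthase, were 2.17-fold (1.89 to 2.49) and 4.24-fold (3.72 to 4.85) higher. None of the lists in this paragraph with at least 3 members had a median apart from random lists in the main setting. The phosphate list was apart with a prior of 5 reads, at percentile 97.9, and by its mean, at 98.7, and ribosomal proteins were apart by their mean, at 1.15. Neither median, with the main prior, was apart when the random lists were matched on length or the lists were shifted along the gene order. The means were not compared in these settings, so whether length or gene order accounts for the results by the mean was not tested.

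Of 39 listed genes of cell envelope and exopolysaccharide 31 were lower, of 23 two-component regulators 17, and of 8 genes of cell division and chromosome replication 6, where 61.4% of all listed features were lower. The two-component and cell division medians were not apart, at percentiles 26.5 and 30.2. The glycosyltransferase genes PCC7418_RS12555 (positions 2780022 to 2781314) and PCC7418_RS12560 were 17.1-fold (12.8 to 24.1) and 17.4-fold (12.7 to 25.0) higher, from 44 to 695 and from 39 to 625 reads. The histidine kinase gene PCC7418_RS17365 was 15.0-fold lower (14.2 to 15.9), and the response regulator gene PCC7418_RS16475 was 6.34-fold higher (6.05 to 6.66). The envelope median, -1.52, was at percentile 5.8 of random lists matched on expression and at 1.01 of lists matched on length as well, the second comparison having been added after the data were seen. It was -1.23 at percentile 42.5 with a minimum of 100 reads and -1.32 at 17.5 with a prior of 5 reads, and the mean stood at 35.3.

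Transcripts of mobile elements and of toxin-antitoxin and CRISPR loci were nearly all lower in the 2.5 M library. Of 34 listed transposase and mobile-element genes 33 were lower, and of 59 listed genes matched for CRISPR and toxin-antitoxin 53. Of the 59, 2 genes, a release factor methyltransferase gene (PCC7418_RS11715) and a cupin domain gene (PCC7418_RS16190), matched by accident and were higher. The toxin-antitoxin and CRISPR median, -1.66, stood at percentile 0.32 of random lists, and was no longer apart at 4.69 when the random lists were matched on length too, or at 3.61 with its 7 genes of at least 500 nt. The mobile-element median, -1.43, stood at percentile 3.43, while the mean was apart. The gene ltrA (PCC7418_RS03210), for a group II intron reverse transcriptase/maturase, took 1.94% of the reads at 0.5 M and 0.297% at 2.5 M and was 6.34-fold lower (6.28 to 6.39), and tnpB PCC7418_RS06260 was 12.5-fold lower (11.9 to 13.1). The HicB family antitoxin gene PCC7418_RS18470 was 16.9-fold lower (10.4 to 31.5). Whether copies of mobile elements share sequence was not checked, so single values are uncertain. In all, the medians of 4 of 22 lists with at least 3 members were apart from matched random lists, where about 1.1 would be by chance if genes varied independently. When lists were shifted along the gene order, which keeps neighbours together, 2 were apart; leaving out the members matched by accident instead, 3 were.

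**Figure D3:**
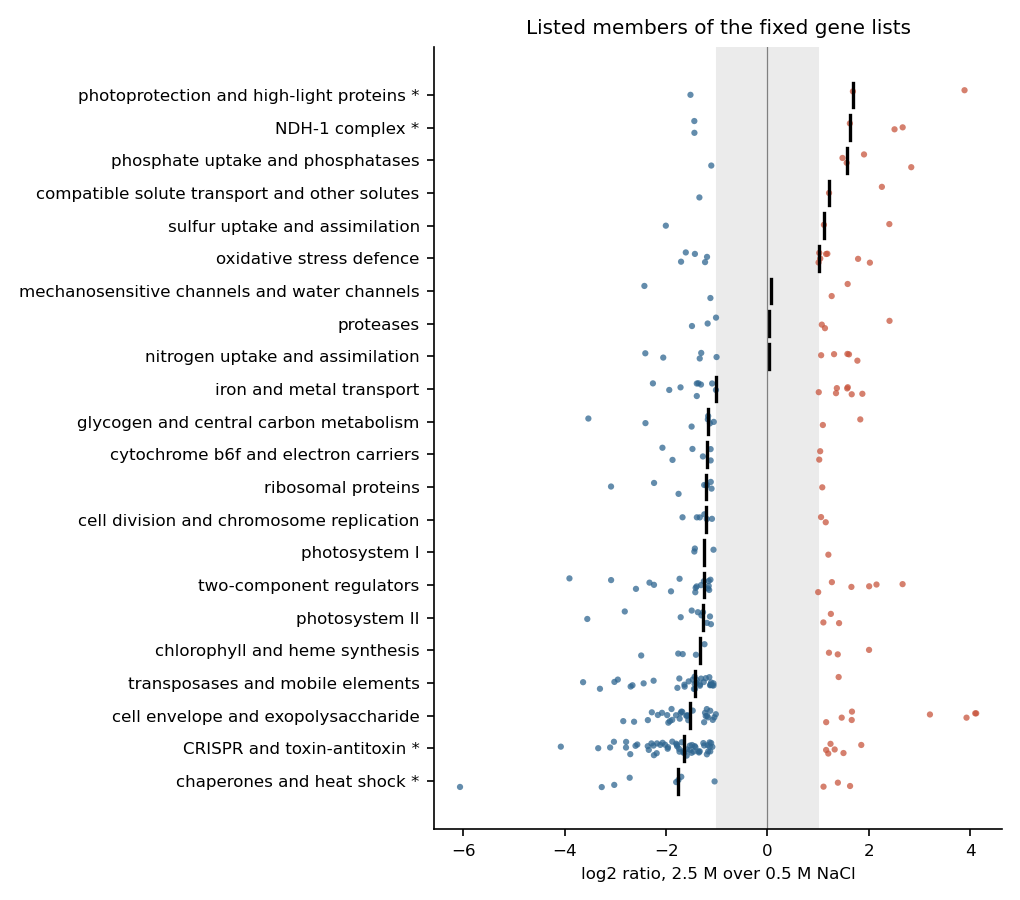
Log2 ratio of the 2.5 M over the 0.5 M library (x axis) for the listed members of the 22 gene lists with at least 3 members (y axis); points are genes, red higher and blue lower, black bars are medians, the grey band is the range under 2-fold that the table leaves out, and asterisks mark the 4 medians apart from random lists. The medians run from -1.76 for chaperones to 1.69 for photoprotection.

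Direction moved with gene length over all listed coding genes, but not in every list. Mobile-element genes, with a median length of 1227 nt, were lower in 33 of 34 cases. The higher one, tnpA PCC7418_RS05410, is 411 nt long. Among listed coding genes 90.3% of those under 300 nt were lower (exact 95% interval 85.3 to 94.1), against 66.4% (60.7 to 71.8) from 300 to under 600 nt. The share was 54.6% (49.5 to 59.6) from 600 to under 1200 nt and 45.1% (39.3 to 50.9) at 1200 nt and over. These intervals treat genes as independent, although neighbouring genes often went the same way, and they cover no variation between libraries. The median listed length was 273 nt in toxin-antitoxin and CRISPR genes, 279 nt in ribosomal protein genes, 175.5 nt in photosystem I and 426 nt in photosystem II, against 1227 nt in mobile elements, 1539 nt in NDH-1 and 1626 nt in chaperones. With random lists matched on length as well as expression, 4 medians were apart, those of chaperones, NDH-1, mobile elements and the cell envelope.

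**Figure D4:**
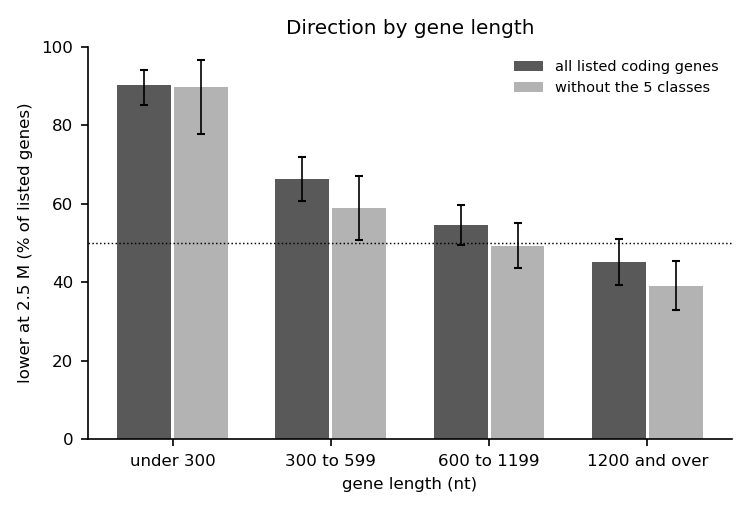
Share of listed coding genes that were lower in the 2.5 M library (y axis, %) by gene length (x axis, nt), for all 1173 coding genes and without hypothetical, DUF, toxin-antitoxin, CRISPR and mobile-element genes. Error bars are exact 95% binomial intervals that treat genes as independent, and the dotted line is 50%. The share drops from 90.3% under 300 nt to 45.1% at 1200 nt and over, and from 89.8% to 39.1% without those genes.

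Among genes with at least 100 reads over both libraries, the highest ratio was that of a hydrogenase maturation protease gene, PCC7418_RS10660 (positions 2376141 to 2376620). It had 163 reads at 0.5 M and 3780 at 2.5 M, 25.4-fold higher (21.7 to 29.9). The gene next to it, PCC7418_RS10655, for a pentapeptide repeat protein, was 17.4-fold higher (15.3 to 20.1). A ferrochelatase gene, PCC7418_RS06680, for the enzyme that inserts iron into protoporphyrin to form heme, was 16.5-fold higher (14.5 to 18.9). Genes for a manganese efflux pump (PCC7418_RS09045) and a CheW chemotaxis protein (PCC7418_RS05605) were 9.39-fold (8.50 to 10.4) and 10.6-fold (8.75 to 12.9) higher. The efflux pump gene was not matched by the list of iron and metal transport. After Hsp20, the lowest ratio among genes with at least 100 reads was that of PCC7418_RS11375, of the hemerythrin family of oxygen-binding proteins. It was 27.9-fold lower (24.5 to 32.1), from 6842 to 223 reads. A gene for a cadherin-like domain protein (PCC7418_RS01875) was 20.4-fold lower (18.3 to 22.9).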

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

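The TMM scaling from listed features, the assumed coefficients of variation, the list settings without accidental matches, with genes of at least 500 nt and with length-matched random lists were chosen after seeing the data; the other settings were planned. No paired analysis was possible because each group holds 1 library. The number of features at least 2-fold higher stayed within 1.5 times the main 458 under the scalings, minimums, priors and interval rules tried, from 342 with the whole counting interval beyond 2-fold to 460, but was 289 and 127 when an exact test with an assumed coefficient of 0.3 or 0.4 was required. The number at least 2-fold lower ranged from 515, with the coefficient of 0.3, to 733 under most settings, and was 176 with DESeq2 factors, 343 with TMM factors, and 296 with the coefficient of 0.4. DESeq2 and TMM factors from the listed features shift all log2 ratios up by 1.18 and 0.61. Both centre a list that lacks features under 2-fold and in which 61.4% of features were lower. With DESeq2 factors 596 features lay above 0 and 597 below. For the number of list medians apart, 3 to 6 were found against the main 4, and 2 (NDH-1, and CRISPR and toxin-antitoxin) when lists were shifted along the gene order; the cause was not tested. With DESeq2 factors the median of iron and metal transport became 0.17 and that of glycogen and central carbon metabolism 0.013, and 7 of 124 named genes turned to higher: PCC7418_RS01545 at 0.0030, PCC7418_RS04230 at 0.056, PCC7418_RS16135 at 0.074, PCC7418_RS16130 at 0.080, PCC7418_RS03395 and PCC7418_RS18700 at 0.12, and PCC7418_RS20085 at 0.16, as the shift by construction gives. With coding genes of at least 500 nt only, the median of iron and metal transport became 1.01, that of photosystem II went from -1.27 to -0.0066 and that of nitrogen from 0.03 to 1.06; members of these lists go both ways. Depth limits genes with few reads, such as PCC7418_RS17760 with 15 reads at 0.5 M.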

Other observations

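The tests of mobile elements, of neighbours and of the gene families and terms named here were chosen after the result was seen, as were the subsets of pairs by length; the test on all pairs and the test without short classes of genes were chosen after direction was seen to move with length, but before their own results were seen. Of 13 families looked at, genes for restriction and DNA modification were lower in the 2.5 M library in 16 of 16 cases and sulfotransferase genes in 12 of 12. Uma2 family endonuclease genes, another family, were lower in 13 of 17 cases, a share at percentile 89.1 of random lists. The HindVP family restriction endonuclease gene PCC7418_RS18040 was 14.0-fold lower and the DNA cytosine methyltransferase gene next to it, PCC7418_RS18035, was 12.7-fold lower, from 1567 to 112 reads. A stretch of nitrogen fixation genes, PCC7418_RS08830 to PCC7418_RS08860 on the plus strand, was lower throughout. In it nifU was 11.9-fold, nifH 5.99-fold, nifD 2.86-fold and nifK 2.16-fold lower, while nifS upstream, with 34 and 72 reads, was 2.30-fold higher. Elsewhere a Mo-dependent nitrogenase C-terminal domain gene, PCC7418_RS07260, was 2.93-fold higher, from 3303 to 8840 reads. Over the family 7 of 9 listed genes were lower, a share at percentile 78.8 of random lists. Of 38 listed ABC transporter genes 24 were higher, among them 4 neighbours, PCC7418_RS04415 to PCC7418_RS04430, that include a carbohydrate and a sugar permease gene, at 2.62-fold to 3.65-fold. By the terms in the authors' deposited table, 39 of 59 listed features with transporter activity and 42 of 63 with the term membrane were higher, and 37 of 69 with the term membrane part, against 358 of 753 features with any term. Features without a term were lower in 76.8% of 440 cases. Of 16 listed tRNA genes 15 were lower, and 3 of 3 listed 5S ribosomal RNA genes were higher. How the libraries were made from short and ribosomal RNA is not given in the sources used here.

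Short listed genes were mostly lower in the 2.5 M library. An excess of short toxin-antitoxin, CRISPR, mobile-element, hypothetical and DUF genes does not account for it as the whole cause: without them, the share lower among coding genes under 500 nt was still 22.8 percentage points above that of longer ones, outside the -8.53 to 9.23 of 10000 shuffles of length. These shuffles treat genes as independent, although neighbouring genes often went the same way, so their range may be too narrow. A loss of short transcripts in the 2.5 M library, as from a difference in RNA or library size selection, remains open: in 262 pairs of listed neighbours on 1 strand, the shorter gene had the lower log2 ratio in 146, by a median of -0.084, just below the bound of -0.070 from random sign flips. The difference was -0.30, with the shorter gene lower in 41 of 67 pairs, where it was under 300 nt, and -0.43, with the shorter gene lower in 17 of 23 pairs, where the longer gene was also at least 600 nt. These pairs do not decide it, because neighbours at most 100 nt apart may share a transcript. A loss of short transcripts would then act on both genes alike. Consecutive pairs can also share a gene, whereas the sign flips treat all pairs as independent. Salinity itself was not separated from a loss of short transcripts, as each group holds 1 library.

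Mobile elements, toxin-antitoxin and CRISPR genes were lower in 92.4% of 92 cases with at least 20 reads, 2 of which, both higher, were matched by accident. Gene length does not account for this as the whole cause, since random lists matched on length and expression had 59.8% to 76.1% lower members. The lists shifted along the gene order had 51.1% to 70.7%, so the grouping of members along the chromosome would rarely give such a share by itself. A shift moves the lists away from their own regions, and members were not compared with their own neighbours. Their position in regions of lower neighbours therefore stays open. Wrong placement of reads between near-identical copies stays open and untested, as does a response of these genes to salinity.

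Neighbouring listed genes at most 500 nt apart went the same way in 92% of 400 same-strand pairs, against 47.5% to 57.5% after shuffling. Transcription in shared units on 1 strand may account for most of this. Opposite-strand pairs also shared their direction in 66.9% of 145 cases. The upper bound was 60.7% from shuffles and 62.1% from shuffles within length classes, both of which treat genes as independent. Whether shared units account for all of it stays open, because it is not known whether counting used strand. Loss of a stretch of chromosome in part of the 2.5 M cells stays open: in both runs tied as the longest of lower neighbours with genes on both strands, PCC7418_RS00500 to PCC7418_RS00540 and PCC7418_RS14170 to PCC7418_RS14210, the 9 genes had standard deviations of 0.71 and 0.95 in log2 ratio, within the 0.28 to 1.20 of random lower sets, but such a loss shifts all genes of a stretch alike and leaves this spread unchanged, so the comparison decides nothing. Counting without strand would also give opposite-strand neighbours like directions where genes overlap, which was not tested.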
